A study of Mus musculus with 4 samples.

How the data were processed

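Regulatory T cells, marked by a green fluorescent reporter of the transcription factor Foxp3, had been sorted from the spleens of C57Bl/6 mice and activated overnight with an antibody to CD3, per the labels. The culture also held either rat immunoglobulin G, the isotype control, or OX86, a rat antibody that activates the costimulatory receptor OX40. Total RNA was amplified into biotinylated complementary RNA and hybridised to Illumina bead arrays, with 2 arrays in each group. The labels number the arrays of each group as replicates without saying whether they came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. All 4 arrays lay on a single slide, so slide could not differ between the groups.

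The deposited table gave, for each array and probe, a signal intensity on a linear scale and a detection p-value. BeadStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The intensities had no negative values and a lowest value of 194.3 or more on each array, so no background had been subtracted from them. The deposited detection p-values moved in steps that correspond to 798 negative control beads. A second deposited table held the authors' processed intensities, also linear. Against the first table, the rank correlation was 1 on each of the 4 arrays, and at least 99.98% of values lay within 1% of a quantile normalization made here without background correction. The medians in the authors' processed table were 314.9, 314.7, 314.4 and 314.8 for isotype 1, OX86 1, isotype 2 and OX86 2, and no log transform, centring or ratio had been applied to it. These values served only as an alternative.

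Signals were corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. The function fitted a normal-exponential background model with control statistics inferred from the detection p-values, added an offset of 16, applied quantile normalization and took log2. Probes were tested where the detection p was under 0.05 on at least 2 of the 4 arrays, which kept 13338 of 25697 probes. Gene names came from the platform annotation. It gave 23978 probes a single symbol, 0 probes several and 1719 probes none. Entrez numbers of 23962 probes matched a RefSeq table of assembly GRCm38.p6, used only for names, and 0 symbols needed updating. The tested probes with a symbol numbered 12477 and covered 9361 genes. Probe sequences were not used here, so hybridisation to related genes such as the Bcl2a1 or guanylate-binding protein families was not assessed, and no genome coordinates are given.

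OX86 arrays were compared with isotype arrays in limma (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Log2 changes are OX86 minus isotype, with 95% intervals from the moderated variance. The residual degrees of freedom were 2 and the prior degrees of freedom 3.68. Adjusted p-values for gene lists came from camera in limma with a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over 20 lists. The lists, the tests of the comparison and the alternatives other than array weights were fixed before the data were examined. They covered functions of activated T cells, signs of RNA handling and markers of cell types that a sort could carry along. Each gene entered a list through its brightest probe by the mean over the 4 arrays, and a gene could be in more than 1 list. The same lists were tested with camera under an estimated correlation and with fry. Under an estimated correlation camera refers each list to the 2 residual degrees of freedom, so hardly any list could pass.

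Genes were named by a rule with 4 parts. Tnfrsf4, Foxp3, Irf1, Il10, Il2ra and Ctla4 were reported whatever their result. Up to 12 genes in each direction were to be those past the threshold with the largest change and with the groups not overlapping. Places left over went to genes with the smallest unadjusted p in that direction whose groups did not overlap, reported as values that did not pass. Up to 4 members of each list with the smallest unadjusted p could be named. A gene with several tested probes is given by its brightest, and 5 of the 23 such named genes had probes of opposite sign. Where a probe was not detected on either array of a group, the change is given as a bound. The bound sets the mean of the brighter group against the mean over the dimmer group's arrays of the higher of the lowest detected signal and the probe's own signal.

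The calculations were tested on data simulated for 2 against 2 arrays over 13338 probes, with 200 probes changed in each of 10 draws. At the threshold, 40.8% of probes changed 2-fold were recovered, 99.2% of those changed 4-fold, and 100% of those changed 8-fold or 16-fold. False calls came to 12.8 per draw. The simulated probes were independent and had the same spread on each array, with no array standing apart. The changed probes were divided equally among 2-fold, 4-fold, 8-fold and 16-fold changes, and the larger changes ease the adjusted threshold for the 2-fold ones. Recovery in the real data may therefore be lower. There 46 probes had a log2 change of 1 or more in size and 0 passed. The 40.8% is thus not an estimate of the power for 2-fold changes here. Alternatives covered the background correction, the normalization, the filter on dim probes, the authors' processed values, averaging of probes per gene, the variance model, the replicate number as a block, leaving out each array in turn, the correlation between genes and the list test. Weights per array were added after the data had been examined.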

Results

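Gene expression was measured in splenic regulatory T cells activated overnight through CD3 with either an isotype antibody or OX86, an agonist antibody to the costimulatory receptor OX40. Each group had 2 arrays. The median signal was 324.7 and 296.4 on isotype arrays 1 and 2, and 316.0 and 321.8 on OX86 arrays 1 and 2. Probes detected at p under 0.05 numbered 13682 (53.2%), 11800 (45.9%), 12890 (50.2%) and 12996 (50.6%) on isotype 1, isotype 2, OX86 1 and OX86 2. Isotype 2 stood apart from the other arrays: across tested probes its correlations with isotype 1, OX86 1 and OX86 2 were 0.968, 0.969 and 0.972, against 0.981 to 0.985 for the pairs without it. The SD of its log2 difference from the mean of the other 3 arrays was 0.438, against 0.307 to 0.318 for each of the others. Genes are not independent replicates in these correlations, and the number of arrays limits the precision of every comparison.

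The comparison asked which transcripts differ when OX40 is engaged during activation of regulatory T cells. Genes of cholesterol synthesis were higher as a group with OX86, by a mean log2 change of 0.25 over 13 genes, and interferon-regulated genes were lower, with a mean log2 change of -0.16 over 28 genes. Neither group call held by fry or when the correlation between genes was estimated. The test with an estimated correlation has 2 residual degrees of freedom and could pass few lists. For the interferon list the estimated correlation, 0.233, was also above the preset 0.01, which raises p by itself. Without isotype 2 the interferon mean was -0.06 and the cholesterol mean 0.21, and neither list passed. No single gene passed the test. Foxp3, Ctla4, Il2ra and Il10 each differed between the groups by less than 0.10 on the log2 scale. The chemokine genes Ccl4 and Xcl1 had log2 changes of -1.02 and -0.99, which did not pass, and Xcl1 had -0.58 without isotype 2. Leaving out a single array moved the log2 change by over 1.5 times, or turned its sign, for 70 of the 107 genes under the naming rule.

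Of 13338 tested probes, 0 passed in limma with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 444 probes, 231 higher and 213 lower with OX86, or 3.33% of those tested, against 666.9 probes given by chance. Without isotype 1 that count was 1536, and 0 probes passed, with a smallest adjusted p of 0.325 in limma with Benjamini-Hochberg adjustment. The groups did not overlap for 1850 probes higher and 1742 lower with OX86, 26.9% together, where chance gives 33.3% for 2 against 2. The median half-width of the 95% interval of a log2 change was 0.56, with quartiles of 0.50 and 0.69. A log2 change of 1 or more in size was measured for 46 probes.

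Tnfrsf4, which encodes OX40, had normalized log2 signals of 13.52 and 13.61 on the isotype arrays and 13.67 and 13.76 on the OX86 arrays. Its log2 change was 0.15, with a 95% interval of -0.32 to 0.63. Foxp3, the transcription factor that defines regulatory T cells, had a log2 change of 0.08 (95% interval -0.42 to 0.58), and its 3 probes ranged from 0.03 to 0.10. The inhibitory receptor gene Ctla4 differed by -0.00 (-0.50 to 0.50). Irf1, a transcription factor of interferon responses, had a log2 change of -0.23 (-0.79 to 0.33) at its brightest probe. All 5 Irf1 probes were lower in mean with OX86, from -0.77 to -0.15, none passed, and the brightest had -0.055 without OX86 1. The interleukin-10 gene Il10 had a change of -0.01 (-0.57 to 0.55), and Il2ra, the interleukin-2 receptor alpha chain, one of -0.02 (-0.58 to 0.54). With median scaling in place of quantile normalization the differences of Ctla4, Il10 and Il2ra had the opposite sign. The Il10 and Il2ra probes gave deposited signals within 1.09% of each other on every array, so the values of these genes are uncertain.

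**Figure D1:**
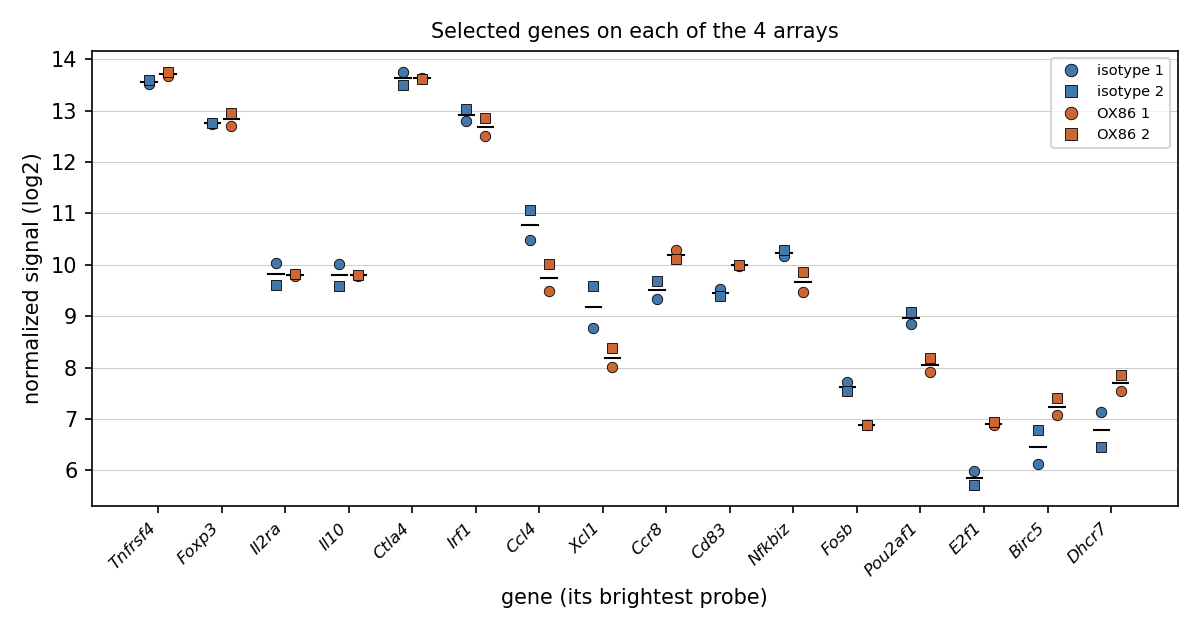
Normalized log2 signal (vertical axis) of selected genes at their brightest probe on the 2 isotype arrays (blue) and the 2 OX86 arrays (orange), with circles for replicate 1, squares for replicate 2 and a short line at each group mean. Ccl4 lay at 10.48 and 11.06 on the isotype arrays and at 9.48 and 10.02 on the OX86 arrays, while Ctla4 had a group difference of -0.00; none of these genes passed the test.

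The genes with the smallest unadjusted p whose groups did not overlap are given as values that did not pass. Higher with OX86 were Dkkl1, E2f1, Tbx22, Rundc3a, Zfp74, Paics, Trim69, Olfr816, Bnc1, Brwd3, Nectin4 and Rasgrp2. Lower were Obox7, Atp6v1g3, Tmem159, Trappc12, Card10, Hormad2, Gsta1, Rbmxl2, Ip6k2, Pou2af1, Brinp1 and Cyp4f39. In each direction, 8 of the 12 were not detected on either array of the dimmer group. As bounds, those 8 higher genes were at least 1.09-fold to at least 1.59-fold higher, and the 8 lower genes at least 1.16-fold to at least 1.92-fold lower. Log2 changes of the genes detected on at least 1 array of each group ran from 0.86 (Rasgrp2) to 1.15 (Paics) and from -1.11 (Ip6k2) to -0.89 (Gsta1). Of these, E2f1, Paics, Trim69 and Rasgrp2 were each detected on only 1 isotype array, and Ip6k2 on only 1 OX86 array. Their changes thus include a value below detection. Pou2af1, a transcriptional coactivator best known from B cells, was the only one of these 24 genes with a mean log2 signal above 8. Its isotype arrays read 8.85 and 9.09 and its OX86 arrays 7.92 and 8.18, a log2 change of -0.92 (95% interval -1.45 to -0.39).

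Cholesterol synthesis genes were higher in mean for 12 of 13 tested members, and the list passed in camera (limma) with a Benjamini-Hochberg adjusted p = 0.00995. With an estimated correlation, which was -0.061 for this list, its unadjusted p was 0.0734 and its adjusted p = 0.948, the adjusted value of all 20 lists. A correlation below the preset 0.01 cannot have raised p. That test rests on 2 residual degrees of freedom, so its result decides little for this list. By fry, which asks whether members move on balance in a single direction, its adjusted p = 0.284. Relative to their mean over the 4 arrays, the genes stood at -0.08 and -0.18 on isotype 1 and isotype 2, and at 0.10 and 0.16 on OX86 1 and OX86 2. Dhcr7, which encodes the enzyme of the final reduction step, had a log2 change of 0.90 (95% interval 0.18 to 1.63), and one of 0.57 without isotype 2. Mvd of the mevalonate pathway had 0.50 (-0.506 to 1.504), with 0.0076 without OX86 2 and 0.15 without isotype 2, and Stard4, a sterol transport protein, 0.33 (-0.14 to 0.80). Nsdhl, with 0.51 (-0.02 to 1.03) at its brightest probe, had 4 probes that differed in sign. The members past the threshold numbered 0, over all probes and adjusted over the list alone. The call was lost without isotype 1, isotype 2 or OX86 2, where a group kept a lone array and the mean changes were 0.30, 0.21 and 0.22. It was also lost with probes averaged per gene (camera, Benjamini-Hochberg adjusted p = 0.0559), with a mean change of 0.22. The mean change was 0.12 without background correction and with the authors' processed values, where the list still passed.

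Interferon-regulated genes were lower in mean for 23 of 28 members, with adjusted p = 0.00995 in camera (limma, Benjamini-Hochberg). With an estimated correlation, 0.233 for this list, the unadjusted p was 0.289 and the adjusted p = 0.948, and by fry the adjusted p was 0.946. A correlation above the preset 0.01 raises p, so the loss of this call does not rest on the residual degrees of freedom alone. The inducible GTPase gene Igtp had a log2 change of -0.56 (95% interval -1.35 to 0.23), the ubiquitin-like modifier Isg15 -0.46 (-1.12 to 0.19), the transcription factor Irf8 -0.35 (-0.88 to 0.17) and the nucleic acid sensor Zbp1 -0.35 (-0.90 to 0.19). In 5 of the 28 members both OX86 arrays lay below both isotype arrays, as in 1742 of all 13338 tested probes. Chance gives 33.3% for both directions together, so this count adds little. Past the threshold were 0 members, over all probes or adjusted over the list alone. Relative list means were -0.02 and 0.19 on isotype 1 and isotype 2, and -0.13 and -0.03 on OX86 1 and OX86 2. Without isotype 2 the mean change was -0.06, and without OX86 1 it was -0.11. It was -0.26 without isotype 1 and -0.21 without OX86 2, and a group kept a lone array in each of these fits. Isotype 2 was the array with the largest departure from the other 3.

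Cell cycle genes were higher in mean for 21 of 27 members, with a mean log2 change of 0.17 that did not pass (camera, Benjamini-Hochberg adjusted p = 0.0718). The transcription factor E2f1, which drives genes of DNA synthesis, had a log2 change of 1.07 (95% interval 0.56 to 1.57), although isotype 2 was below detection for it. Birc5, needed for chromosome segregation, had 0.79 (0.08 to 1.497) at its brightest probe, and 0.64 and 0.095 at its other probes. Tk1 and Tyms, both of thymidylate supply, had 0.36 (-0.12 to 0.83) and 0.35 (-0.11 to 0.82). Adjusted over the list alone, 0 members passed, and the smallest adjusted p there was 0.0632, that of E2f1 in limma with Benjamini-Hochberg adjustment. The list passed under 5 other settings. In camera with an estimated correlation, on 2 residual degrees of freedom, its adjusted p = 0.948, the value of every list. Apoptosis regulators had a mean change of 0.16 over 16 members, 9 higher and 7 lower (camera, Benjamini-Hochberg adjusted p = 0.283), with 0.61 (-0.26 to 1.48) for the survival gene Bcl2l1. The Bcl2l1 value was 0.13 without OX86 1, and its other probes had 0.52 and 0.014. The apoptosis mean was 0.063 without isotype 2 and 0.25 without isotype 1.

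Genes of regulatory T-cell identity and suppressor function had a mean log2 change of 0.09 over 21 members, 14 higher and 7 lower, and did not pass (camera, Benjamini-Hochberg adjusted p = 0.283). Their largest values among named members were 0.42 (95% interval -0.33 to 1.17) for the integrin gene Itgae and 0.36 (-0.23 to 0.94) for the inhibitory receptor Lag3. All 6 Itgae probes were higher in mean with OX86, from 0.39 to 1.23, while its brightest had 0.085 without OX86 2. Helper lineage transcription factors had a mean change of 0.13 over 9 members, 7 higher and 2 lower (adjusted p = 0.363), with 0.25 (-0.25 to 0.75) for Gata3 and 0.30 (-0.27 to 0.87) for Id3. Both lists passed without OX86 1, with mean changes of 0.20 and 0.30 (camera, Benjamini-Hochberg adjusted p = 0.0335 for each), and without OX86 2 their mean changes were -0.017 and -0.037. Over all 4 arrays each had an adjusted p = 0.948 in camera with an estimated correlation, the value of every list on 2 residual degrees of freedom. Their estimated correlations were 0.174 (identity) and 0.372 (helper factors), above the preset 0.01, which also raises p. Quiescence and homing genes had a mean change of 0.08 over 11 members (adjusted p = 0.552), with 0.35 (-0.14 to 0.84) for Cxcr4 and 0.19 (-0.30 to 0.67) for Klf2, and the mean turned to -0.0010 without isotype 2.

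Effector cytokine and chemokine genes had a mean log2 change of -0.14 over 11 members, 5 higher and 6 lower (camera, Benjamini-Hochberg adjusted p = 0.363). That mean was 0.029 without OX86 1, 0.027 without isotype 2, -0.30 without isotype 1 and -0.31 without OX86 2. Ccl4, a chemokine that attracts T cells and macrophages, had a change of -1.02 (95% interval -1.76 to -0.27), and its other probe one of -1.11. The lymphotactin gene Xcl1 had -0.99 (-1.79 to -0.18), and -0.58 without isotype 2. Adjusted over the list alone, the smallest adjusted p was 0.135 in limma with Benjamini-Hochberg adjustment. Early activation genes had a mean change of -0.07 over 21 members, 9 higher and 12 lower (adjusted p = 0.363), with -0.74 (-1.23 to -0.26) for the AP-1 gene Fosb, -0.36 (-0.91 to 0.19) for Nr4a2 and 0.34 (-0.38 to 1.07) for Irf4, and the mean turned to 0.012 without isotype 1. Glycolysis genes had a mean of -0.09 over 14 members, 4 higher and 10 lower (adjusted p = 0.363), with -0.55 (-1.06 to -0.04) for the lactate transporter Slc16a1 and -0.36 (-0.996 to 0.27) for hexokinase Hk2. The glycolysis mean was 0.0036 without isotype 2 and -0.18 without isotype 1.

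NF-kB pathway genes and targets, which lie downstream of OX40, went both ways. Over 22 members, 10 were higher and 12 lower, with a mean log2 change of 0.01, a median of -0.06 and a camera direction of lower (Benjamini-Hochberg adjusted p = 0.947). Cd83 had a change of 0.53 (95% interval 0.06 to 1.01), and Nfkbiz, an atypical inhibitor of NF-kB, had -0.57 (-1.12 to -0.01). Chemokine receptors and adhesion genes divided evenly, 5 higher and 5 lower, with 0.69 (0.14 to 1.23) for Ccr8 and -0.47 (-0.96 to 0.02) for the integrin gene Itgav. Their list did not pass in camera (adjusted p = 0.947) nor in fry for change in either direction (adjusted p = 0.295). Costimulatory and inhibitory receptors had a mean of 0.02 over 19 members (adjusted p = 0.947), with -0.44 (-1.02 to 0.15) for Cd160, -0.39 (-0.94 to 0.17) for Cd274 and -0.35 (-0.93 to 0.22) for Pdcd1, and the mean was 0.0080 without isotype 1. The unfolded protein response list had a mean of 0.03 over 21 members (adjusted p = 0.947). In these lists too, 0 members passed, over all probes or adjusted over the list alone.

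**Figure D2:**
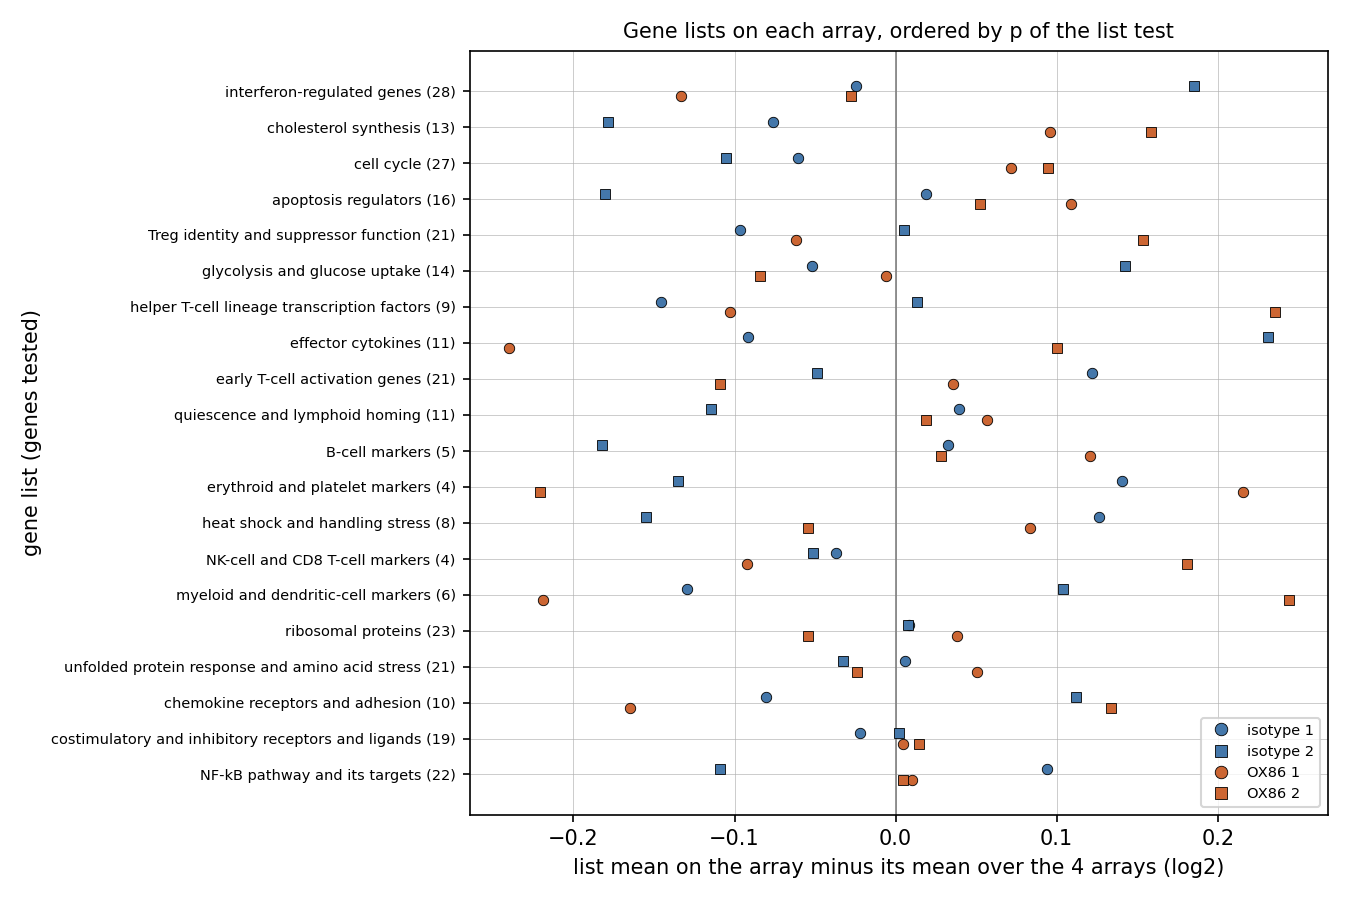
Mean log2 signal of each of the 20 gene lists on each array, minus the list's mean over the 4 arrays (horizontal axis), with the number of genes tested in brackets, isotype arrays in blue and OX86 arrays in orange, circles for replicate 1 and squares for replicate 2. Cholesterol synthesis genes stood at -0.08 and -0.18 on the isotype arrays and 0.10 and 0.16 on the OX86 arrays, while interferon-regulated genes stood at 0.19 on isotype 2 and between -0.13 and -0.02 on the other arrays.

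Markers of other cell types and of RNA handling did not separate the groups by test. Of 62 genes fixed in the lists for other cell types, 19 were tested. B-cell markers had a mean log2 change of 0.15 and a median of -0.11 over 5 genes (camera, Benjamini-Hochberg adjusted p = 0.811), with 0.81 (95% interval 0.13 to 1.49) for Ms4a1, which was near the detection limit, and -0.26 (-0.96 to 0.43) for Cd79a. The B-cell mean was 0.049 without isotype 2, 0.23 without isotype 1 and -0.18 over probes detected on all 4 arrays. Myeloid and dendritic-cell markers had a mean of 0.03 and a median of -0.09 over 6 genes (adjusted p = 0.947), with 0.56 (-0.12 to 1.23) for Cd74. NK-cell and CD8 T-cell markers had a mean of 0.09 over 4 genes (adjusted p = 0.947). Erythroid and platelet markers had a mean of -0.01 over 4 genes with a camera direction of higher (adjusted p = 0.947), and the haemoglobin gene Hba-a1 read 10.69 and 9.26 on the isotype arrays and 10.11 and 9.14 on the OX86 arrays. Heat shock genes had a mean of 0.03 over 8 genes and ribosomal protein genes one of -0.02 over 23 genes (adjusted p = 0.947 for each), the latter being 0.0063 without background correction. Leaving out a single array turned the sign of the mean in each of these lists except the B-cell markers, and also for the NF-kB, chemokine receptor and unfolded protein response lists.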

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

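Weights per array were the only alternative chosen after the data had been examined. They came to 0.761 on each isotype array and 1.31 on each OX86 array, so this alternative did not weigh isotype 2 below isotype 1. The count of probes past the threshold in limma with Benjamini-Hochberg adjustment was 0 under each of 15 alternatives, with 193 (without OX86 1) to 1536 (without isotype 1) probes at an unadjusted p under 0.05. The smallest adjusted p was 0.325, without isotype 1, the others 0.9996 or more. Against 444 as reported, the unadjusted count was 196 without background correction, 195 with the authors' values, 243 with an intensity trend, 232 without OX86 2, 236 for probes detected on all 4 arrays and 865 with no filter. Leaving out an array leaves a lone sample that is assumed to vary like the other group.

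The lists passing in camera numbered 2, against 4 without background correction, 4 with the authors' values, 4 with an intensity trend, 1 with probes averaged per gene, and 0 with an estimated correlation, by fry in a single direction and by fry in either direction. Leaving out each array gave 0 (without isotype 2) to 3 (without OX86 1). Interferon-regulated genes passed in 13 of 18 settings and cholesterol synthesis in 11, each with its direction kept in all 18. The interferon value of -0.16 and the cholesterol value of 0.25 were not past the threshold with an estimated correlation or by either form of fry. Adjusted p in camera or fry over all settings ran from 0.000175 to 0.983 for interferon and from 0.000959 to 0.948 for cholesterol. Leaving out each array gave -0.26 to -0.058 for interferon and 0.21 to 0.30 for cholesterol, and fewer arrays went into those tests. Cholesterol was 0.22 with probes averaged per gene, and 0.12 (still passing) without background correction and with the authors' values. Cell cycle passed without background correction (0.072), with the authors' values (0.072), with normexp at an offset of 50 (0.11) and with an intensity trend (0.17). Regulatory T-cell identity passed without background correction (0.084), with the authors' values (0.084), with an intensity trend (0.091) and without OX86 1 (0.20, down to -0.017 without OX86 2). Helper lineage factors passed without OX86 1 (0.30, down to -0.037 without OX86 2). The cause was not tested for these changes.

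The labels do not say what a shared replicate number stands for, and a correlation of deviations of 0.0655 over 2 pairs cannot settle it. Dividing the arrays by replicate number gave 7.35% of probes at an unadjusted p under 0.05 in limma, the highest share of the 3 divisions. With the replicate block, 0 probes passed and 522 had an unadjusted p under 0.05, and 3 lists passed, cell cycle among them (0.17, adjusted p = 0.0476 in camera). Of 340 list values under alternatives, 318 stayed on the same side of the threshold and 0 reversed. The direction given by the list test changed with no pass in either setting for 39, in 13 lists. These counts leave out the effector, early activation and quiescence lists, whose means turned sign without some array while the test's direction was kept in all 18 settings. Of 1577 values of 107 named genes, 38 changed sign and 0 passed. The robust prior was not run for lists, since camera has no such setting. Of the leading genes in each direction, 8 of 12 were undetected in a group, which leaves a bound.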

Other observations

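Leaving out each array was planned, but the test on bright probes and the use of the list values without isotype 2 to weigh isotype 2 as their source were chosen only after the results were seen.

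Beyond the lists, some array features stood out as values. Of 5 probes for Actb, a beta-actin gene often used as a reference, 2 ranged over 2.77 and 2.51 on the log2 scale across the arrays. The wider of them read 8.91 on isotype 1, 9.84 on OX86 1, 11.68 on isotype 2 and 10.64 on OX86 2. The narrower read 8.79, 9.74, 11.30 and 10.43 in the same order. Both were higher on replicate 2 than on replicate 1 in each group, with the larger gap between the isotype arrays. The other 3 ranged over 0.26 to 0.47. These probes were picked after their values were seen.

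Fewer probes than chance had a small unadjusted p, 3.33% of those tested, with 0.190% among probes with a mean log2 signal of 8 or more and 6.16% among the others, in a fit with a single prior variance. Compression of dim probes is argued against, since with an intensity trend in the prior variance these shares were 1.15% and 2.42%, so bright probes fell short in both fits. A pairing by replicate number stays open. With that number as a block the share was 3.91%, under the 5% set beforehand but above 3.33%. The block leaves fewer residual degrees of freedom, so that bound cannot exclude a pairing. A more variable isotype 2 stays open, since the bound of 5% set beforehand does not suit fits on 3 arrays, which fell on both sides of it: 3.18% without isotype 2, 11.5% without isotype 1, 1.45% without OX86 1 and 1.74% without OX86 2. The other ways of dividing the 4 arrays into 2 and 2 gave 7.35% and 5.92%, so differences between arrays that do not follow the treatment also remain open.

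For interferon-regulated genes, lower with OX86, isotype 2 as the source is a candidate explanation, since without it the mean log2 change was -0.058. For cholesterol synthesis genes, higher with OX86, that explanation is argued against in size, since the change without isotype 2 was 0.21, although the call ended with fewer arrays. Dividing the arrays by replicate number also called 2 lists in camera with Benjamini-Hochberg adjustment, as many as the labelled division: interferon-regulated genes, higher in replicate 2 by 0.16 (adjusted p = 0.0436; 0.00588 for OX86 with the replicate number as a block), and helper lineage factors, by 0.25 (adjusted p = 0.0454). The remaining division called 0 lists, and cholesterol synthesis genes differed by -0.02 and -0.08 in these 2 divisions. The 3 possible divisions are too few for a share under 0.05, and an OX40 effect on either list stays open.

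The probes for Il10 and Il2ra gave nearly the same deposited signal on each array, 1666 and 1680 on isotype 1, 1125 and 1122 on OX86 1, 705.0 and 706.5 on isotype 2, and 1223 and 1236 on OX86 2. Coincidence among probes of like brightness is argued against, since 1.21% of 2065 such probes (25) had a partner of another gene at least as close. A shared target or a shared annotation error may account for it, which was not tested because probe sequences were not used here. Until that is settled, the values of these genes are uncertain. No biological explanation was tested.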
